A study of Mus musculus with 12 samples.

How the data were processed

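RNA was measured in 12 samples of cultured kidney epithelial cells from C57BL/6 mice, 3 in each of 4 groups. Control cells carried Rosa-CreER, and JNK-deficient cells lacked Jnk1 and Jnk2. Cells of each genotype were either attached or suspended for 4 hours. Per the labels' protocols, RNA was prepared on columns with a DNase step, messenger RNA was purified and made into Illumina libraries, and these were run on a HiSeq 2000. The submitters' processing notes name TopHat, Bowtie, Cufflinks 1.0.3 and Cuffdiff, and the mouse genome build mm10. The versions of the other tools, the annotation and the read length are not given in the sources used here. The samples were assigned to groups from the genotype and culture labels. The labels do not say whether the samples of a group came from separate cultures or animals, so the spread between samples may be technical. The p-values are the authors' own. How far each rests on the spread of that gene's own samples cannot be seen without values per sample.

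The files were 4 tables of 31026 entries each, 1 for each pairwise comparison: genotype in attached cells, genotype in suspended cells, suspension in control cells, and suspension in JNK-deficient cells. Each entry holds a gene symbol, a locus, 1 FPKM value for each of the groups compared (fragments scaled by transcript length and library size, per the submitters' processing notes, which name Cufflinks and Cuffdiff), a log2 ratio, a p-value and a q-value, all as the authors deposited them. The deposited p-values came in steps of 5e-05, with 1 where no test was made, and the deposited q-values equalled Benjamini-Hochberg adjustment of them over the tested entries. A gene symbol stood on more than 1 entry for 593 of 30032 symbols, and 571 entries joined several symbols; reads shared between near-identical or overlapping genes could not be separated. Each entry is called a gene here. FPKM values of the same group in different tables differed by a common factor of at most 0.0895 on the log2 scale and otherwise by an SD of at most 0.00328, so levels are compared within 1 table only. The locus starts were given counting from 0, since 13793 of 30800 matched the GENCODE annotation after adding 1 and 1196 without it; positions are given counting from 1 on mm10.

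The tables hold no value per sample. No SD between samples, no outlier test, no analysis leaving out a sample and no regrouping of samples was possible, and the depth per sample is unknown, so no counting interval or detection floor is given.

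The main test of each pairwise comparison was the authors' own, a q-value below 0.05. Log2 fold changes are suspended over attached or JNK-deficient over control. They are those of the deposited log2 ratio, and no fold is given against a group at 0. The difference of the suspension effects (JNK-deficient minus control) was tested with a z-test. The test written before the data were examined took standard errors from the authors' test statistic, which these tables do not hold. The standard errors were therefore derived after the tables were seen, as the size of the log2 fold change divided by the normal score of its two-sided p-value, where p was at most 0.95. At the lowest p-value this gives an upper bound, which grows with the fold change whatever the spread. Each gene's standard error was taken through the suspension tables and through the genotype tables, as the mean of these 2 routes where p was above its lowest step in all tables, otherwise from the route where it was, and otherwise as the smaller upper bound. The 2 routes had r = 0.982 across 5070 genes on the log scale. Of 12765 genes tested for the difference, 1717 had only an upper bound, and the median standard error was 0.228. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05.

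Gene lists were fixed before the data were examined, from textbook knowledge of anoikis, JNK signalling, detachment, kidney epithelium and the other cell types a kidney culture could hold. For each list, the members past the threshold were counted over all genes tested and adjusted over the list alone. Each list with at least 3 tested members was compared with all other tested genes with limma's cameraPR (limma 3.58.1, R 4.3.3) on the signed normal score of the p-value, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment (FDR) over all lists and comparisons. An estimated correlation needs values per sample and could not be had, so a preset of 0.05 was run instead. Of the other choices, the samples, comparisons, thresholds and naming rule were also set before the data were examined.

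The rule for naming genes took Mapk8, Mapk9 and all BH3-only genes. In each comparison it took the 6 largest rises and the 6 largest falls past the threshold with at least 5 FPKM in the higher and 0.5 FPKM in the lower group, leaving out predicted genes and small RNAs. From each list with at least 3 members past the threshold, it took up to 4 with the largest fold change, not all of which are printed. For the difference it took the 6 genes of largest z in each direction plus list members past the threshold. All genes taken by z had only an upper bound as standard error, so that order does not rank strength of evidence. Largest rises and falls in the text are those under this rule. Some genes under the rule are not reported here. Genes named beside a comparison under whose rule they do not fall were named by the rule of another comparison.

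After the tables were seen, fold changes were also corrected for the GC content and length of the longest protein-coding GENCODE transcript of each gene, by subtracting running medians over 40 bins in 2 passes, and the difference also for level. GC content and length were found for at least 96.0% of genes at 1 FPKM in each comparison. Corrected values were tested with the derived standard errors, or with the 75th percentile of those of genes of like level where p was at its lowest step and that was smaller. Other alternatives were a q-value below 0.01, a floor of 1 FPKM, a minimum change of 1.5-fold, log2(FPKM + 1), standard errors multiplied by 1.5 or taken from level or from 1 pair of tables, and ranks in the list test. Further ones recomputed the Benjamini-Hochberg adjustment, centred fold changes on their median, or left out symbols on more than 1 entry.

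The procedures were tested on simulated data. For the difference over 12765 genes, the z-test called 18 of 50 genes made to differ by a log2 of 1, 31 of 50 by 2 and 39 of 50 by 3, and 1 of 12565 genes left unchanged. The simulated p-values came from the normal model that the derived standard errors assume. This simulation therefore cannot show whether the deposited p-values give true standard errors. For suspension in control cells over 12757 genes, a simulated GC trend (rho = -0.58) fell to rho = -0.01 after correction, which left 7 unchanged genes called in place of 2510 and called 71 of 100 genes of log2 size 1 and 87 of 100 of size 2. CameraPR called 100 of 100 shifted lists and 5 of 2000 unshifted lists among 12000 simulated genes. These genes were independent of each other, so the simulation does not show how often lists of genes that vary together would pass. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.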

Results

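Messenger RNA was measured in mouse kidney epithelial cells to study the role of JNK in anoikis, the death of epithelial cells that lose their attachment. JNK is a stress-activated kinase whose forms JNK1 and JNK2 are encoded by Mapk8 and Mapk9. Control and JNK-deficient cells were grown as attached monolayers or kept in suspension for 4 hours, with 3 samples in each of the 4 groups. The authors' deposited tables give 1 FPKM value per group, a q-value for each of the 4 pairwise comparisons and no value per sample. The depth of each sample is therefore unknown, and the spread of a gene between samples cannot be seen behind its q-value.

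The targeted genes were lower in JNK-deficient cells in both states. Mapk8 (chromosome 14, 33377899 to 33447158 on mm10) was at 8.76 FPKM in attached control and 2.26 FPKM in attached JNK-deficient cells in the authors' deposited table (log2 fold change -1.95, q = 0.000347). In suspended cells it was at 10.9 and 2.52 FPKM in the authors' deposited table (-2.11, q = 0.00099). Mapk9 (chromosome 11, 49846751 to 49886421) was at 12.8 and 8.89 FPKM in attached cells (-0.52, q = 0.000347) and at 29.2 and 17.4 FPKM in suspended cells (-0.74, q = 0.00099) in the authors' deposited tables. The tables hold no value per exon, so the deleted parts were not measured apart from the rest of each gene. Mapk10, the remaining gene of the JNK list, was not tested in any comparison. With suspension, Mapk9 rose in control (1.08, q = 0.000123) and JNK-deficient cells (0.89, q = 0.000144) in the authors' deposited tables, while Mapk8 had fold changes of 0.20 (q = 0.172) and 0.07 (q = 0.808).

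The comparison of suspended with attached control cells asked how these cells respond to loss of attachment. BH3-only genes Bcl2l11 and Bmf, the metallothionein genes Mt1 and Mt2, targets of NRF2 and FOXO and lysosomal genes rose, while genes of DNA replication fell. By the q-value of the authors' deposited table, 8717 of 13386 genes tested changed (65.1%), 4417 up and 4300 down. Of these, 1934 rose and 1685 fell by at least 2-fold. The largest rise among the named genes was that of Mt2, a metal-binding metallothionein, from 0.713 to 340 FPKM (log2 8.90, q = 0.000123) in the authors' deposited table. Rps15a-ps4 (5.92), Mt1 from 2.64 to 155 FPKM (5.88), Aldh1a3, Hmox1 and Srxn1 also stood among the 6 largest rises in the authors' deposited table, and Erdr1, Ercc2, Tmem160, Rpl36, Rnaseh2c and Dpm3 were the 6 largest falls, from -5.60 to -6.85.

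The proteins encoded by BH3-only genes promote apoptosis by acting on other BCL-2 family members. In control cells, 3 of the 7 BH3-only genes tested rose and 3 fell with suspension, with the same counts adjusted over the list alone, and the list as a whole did not stand apart from other genes (FDR = 0.969). Bcl2l11, which encodes Bim (chromosome 2, 128126038 to 128162547), rose from 10.04 to 61.3 FPKM in the authors' deposited table (log2 2.61, q = 0.000123). Bmf (chromosome 2, 118528757 to 118549678) rose from 1.79 to 14.8 FPKM (3.04, q = 0.000123) and Pmaip1, which encodes Noxa (chromosome 18, 66458604 to 66465558), from 75.4 to 131 FPKM (0.80, q = 0.000123) in the authors' deposited table. Bad (chromosome 19, 6938070 to 6951893) fell from 43.0 to 10.1 FPKM (-2.09, q = 0.000123) in the authors' deposited table. Bbc3, which encodes Puma (chromosome 7, 16309583 to 16318334), fell from 13.4 to 3.84 FPKM (-1.80) and Bik (chromosome 15, 83526862 to 83544635) from 14.6 to 8.26 FPKM (-0.83), each with q = 0.000123 in the authors' deposited table. Bid (chromosome 6, 120893119 to 120916820) had a fold change of -0.03 (q = 0.82) in the authors' deposited table, and Hrk was not tested. After correction for GC content and transcript length, Bcl2l11 (2.36), Bmf (2.97), Pmaip1 (0.46) and Bad (-1.41) kept their call, while Bbc3 (-0.02, adjusted p = 0.95) and Bik (0.33, adjusted p = 0.069) did not.

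**Figure D1:**
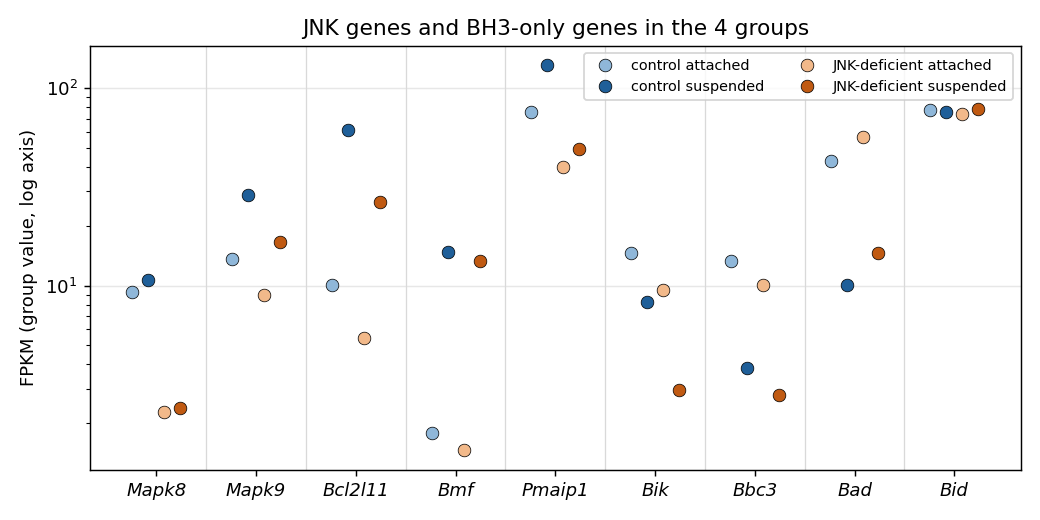
FPKM of Mapk8, Mapk9 and the 7 BH3-only genes tested (x axis) in the 4 groups, on a log axis, as the authors' deposited suspension tables give them, with 1 point per group and no spread between samples. Levels are to be compared within a genotype, and Bcl2l11 and Bmf were higher in suspended than in attached cells of both.

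Of the lists that rose in control cells, the NRF2 targets, which encode antioxidant and detoxifying enzymes, had 9 of 10 members up and 0 down (FDR = 0.00303). Hmox1, the heme oxygenase gene, rose from 30.9 to 1135 FPKM (log2 5.20), Gclc, of glutathione synthesis, by 4.69, Srxn1 by 4.94 and Gsta4 by 4.35 in the authors' deposited table (q = 0.000123 each). FOXO targets had 9 of 10 up and 0 down (FDR = 0.00453), among them Pik3ip1 (4.20), Fbxo32 (3.08), Irs2 (1.74) and Insr (1.46) in the authors' deposited table. Lysosomal and autophagy genes had 9 of 11 up and 0 down (FDR = 0.00525), with Rragd at 4.03, Gabarapl1, an autophagosome protein gene, at 1.74 and Atg9b at 1.21 in the authors' deposited table. Each of these 3 lists had the same counts adjusted over the list alone and stayed past the threshold after the GC and length correction.

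S-phase genes had 0 up and 13 of 17 down in control cells (FDR = 0.00256), with Cdt1, a replication licensing gene, at -1.95, Tyms at -1.69 and Mcm2 at -1.15 in the authors' deposited table. Targets of SRF and other actin cytoskeleton genes had 2 up and 10 of 16 down (FDR = 0.023), with Tpm2 at -1.81, Fhl2 at -1.53 and Actb at -1.51 in the authors' deposited table. Srf itself was at -1.68 there, and at -0.16 (adjusted p = 0.43) after the GC and length correction. Counts adjusted over the list alone were the same for both lists. Of 22 YAP targets, 6 rose and 14 fell (6 and 14 adjusted over the list alone), and the list did not pass (FDR = 0.2). Its most lowered members were Ctgf, a matricellular protein gene, from 815 to 19.4 FPKM (-5.39), Amotl2 (-4.43), Ankrd1 (-4.03) and Cyr61 (-3.41) in the authors' deposited table. Of 22 AP-1 and immediate early genes, 7 rose and 12 fell (7 and 13 adjusted over the list alone; FDR = 0.301), with Junb at -5.51 and Ier2 at -4.08 in the authors' deposited table. Other BCL-2 family genes had 0 up and 5 of 7 down (FDR = 0.0466), with Bok at -3.36, Bcl2 at -2.18, Bax at -1.62 and Bcl2l1, which encodes Bcl-xL, at -1.20 in the authors' deposited table. Epithelial genes had 4 up and 13 of 17 down (FDR = 0.0398), with Pax2 at -3.20, Cldn3 at -3.16 and Krt7 at -1.97 in the authors' deposited table. Counts adjusted over the list alone were the same for these last lists. Neither passed after the GC and length correction (FDR = 0.22 and 0.335), and Bax was then at 0.19 (adjusted p = 0.16). With a preset correlation of 0.05 the SRF, other BCL-2 and epithelial lists did not pass (FDR = 0.0942, 0.097 and 0.136).

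Fold changes with suspension followed the GC content of the transcripts. Across genes, Spearman's rho between fold change and GC content was -0.37 in control and -0.42 in JNK-deficient cells, against -0.01 and -0.12 for the genotype comparisons in attached and suspended cells (genes are not independent replicates). In the tenth of genes with the highest GC content, the median log2 fold change was -1.11 in control and -1.14 in JNK-deficient cells, and 73.2% and 71.8% of the genes fell. After the correction for GC content and length, chosen after the data were seen, 6455 of 8428 calls in control cells and 5186 of 7580 in JNK-deficient cells remained in the same direction, and 183 and 128 passed in the opposite direction.

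**Figure D2:**
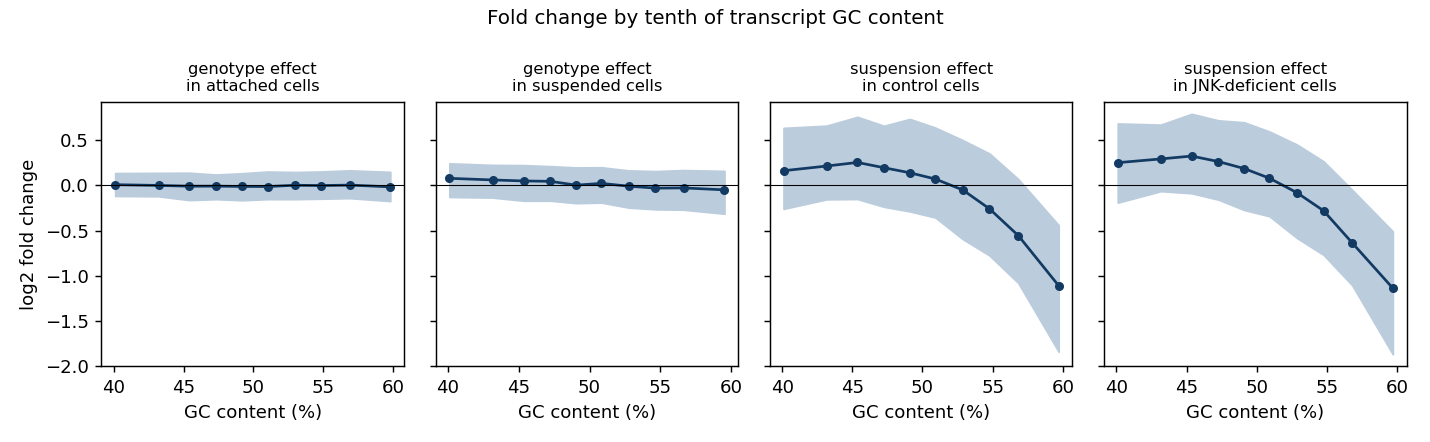
Median log2 fold change (points) of genes in 10 groups of rising transcript GC content (x axis, percent), with 1 panel for each of the 4 comparisons and a band between the quartiles across genes. The medians of both suspension comparisons fell to -1.11 and -1.14 in the group of highest GC content, and those of the genotype comparisons stayed between -0.05 and 0.08.

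Of the leukocyte markers, Ptprc, Csf1r and Cd68 rose with suspension in both genotypes, and the list passed in neither. In control cells 3 of 6 tested markers rose and 1 fell (the same adjusted over the list alone; FDR = 0.46). Ptprc went from 1.14 to 8.92 FPKM, Csf1r from 0.572 to 3.87 FPKM and Cd68 from 15.1 to 34.5 FPKM in the authors' deposited table, while Cd14 fell (-0.79). In JNK-deficient cells 3 of 5 tested markers rose and 1 fell (the same adjusted over the list alone; FDR = 0.471). Ptprc went there from 1.05 to 10.7 FPKM, Csf1r from 1.47 to 7.97 FPKM and Cd68 from 14.0 to 30.8 FPKM in the authors' deposited table.

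In JNK-deficient cells, the comparison of suspended with attached cells asked how the response runs without JNK1 and JNK2. Bcl2l11, Bmf, NRF2 targets and lysosomal genes rose here too, and the lists of cholesterol synthesis genes and interferon-induced genes passed as lower. In control cells 3 of 21 cholesterol genes rose and 12 fell (3 and 13 adjusted over the list alone; FDR = 0.0972), and 3 of 12 interferon-induced genes rose and 6 fell (the same adjusted over the list alone; FDR = 0.563). By the q-value of the authors' deposited table, 7838 of 13136 genes tested changed (59.7%), 4025 up and 3813 down, with 1670 up and 1707 down by at least 2-fold. The 6 largest rises were those of Mt2 (log2 7.32), Rps15a-ps4, Srxn1 (5.62), Hmox1 (5.25), Gstp2 (5.16) and Gsta4 (5.03), and Erdr1, Ercc2, Rnaseh2c, Rpl36, Junb (-5.46) and Tmem160 were the 6 largest falls in the authors' deposited table.

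Bcl2l11 rose from 5.45 to 26.6 FPKM (log2 2.29, q = 0.000144) and Bmf from 1.46 to 13.3 FPKM (3.18, q = 0.000144) in JNK-deficient cells in the authors' deposited table. Pmaip1 rose from 40.05 to 49.4 FPKM (0.30, q = 0.0249), and Bad (-1.95), Bbc3 (-1.86) and Bik (-1.67) fell in the authors' deposited table. That made 3 BH3-only genes of 7 up and 3 down, also adjusted over the list alone (FDR = 0.911). Bcl2l11 (1.95), Bmf (3.15) and Bad (-1.21) kept their call after the GC and length correction, and Pmaip1 (-0.06, adjusted p = 0.69), Bbc3 (-0.09, adjusted p = 0.75) and Bik (-0.48, adjusted p = 0.066) did not.

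NRF2 targets had 10 of 10 members up in JNK-deficient cells (FDR = 0.000498), with Hmox1 from 62.2 to 2361 FPKM and Gclc at 4.56 in the authors' deposited table. FOXO targets had 8 of 10 up and 1 down (FDR = 0.0177), with Fbxo32 at 3.01 and Irs2 at 1.51 in the authors' deposited table. Lysosomal and autophagy genes had 9 of 11 up and 0 down (FDR = 0.00274), with Rragd at 2.60 and Sqstm1 at 2.02 in the authors' deposited table. Among SRF targets and cytoskeleton genes 1 rose and 12 of 17 fell (2 and 12 adjusted over the list alone; FDR = 0.015), with Acta2, which encodes smooth muscle actin, at -2.62 and Zyx at -1.61 in the authors' deposited table. Genes of cholesterol synthesis and uptake had 2 up and 14 of 21 down (FDR = 0.00303), with Mvd at -2.90 and Lss at -1.64 in the authors' deposited table. Interferon-induced genes had 1 up and 11 of 12 down (FDR = 0.000894), with Isg15 at -2.40, Usp18 at -1.89, Irf7 at -1.60 and Ifit3 at -1.52 in the authors' deposited table. Counts adjusted over the list alone were the same except where given, and these 6 lists also passed after the GC and length correction. Other BCL-2 family genes had 0 up and 5 of 7 down, also adjusted over the list alone (FDR = 0.0331; 0.202 after the correction). With a preset correlation of 0.05 the SRF, FOXO and other BCL-2 lists did not pass (FDR = 0.0764, 0.0626 and 0.0764). S-phase genes had 0 up and 8 of 17 down (FDR = 0.0709) and epithelial genes 4 up and 12 of 17 down (FDR = 0.0618), with the same counts adjusted over the list alone, and neither list passed.

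Most of the response to suspension was found in both genotypes. Among 12855 genes tested in both, 3401 rose in both and 3370 fell in both, against 1285 and 1257 for independent lists; 34 rose in control and fell in JNK-deficient cells, and 9 did the opposite. Fold changes had Pearson's r = 0.92 and Spearman's rho = 0.91 across 12797 genes, which are not independent replicates, and the comparisons share no libraries. With calls corrected for GC content and length, 2958 rose in both and 2729 fell in both (1072 and 949 for independent lists; r = 0.91).

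The genotype comparison in attached cells asked what differs between the genotypes before detachment. JNK-deficient cells had lower levels of Jun, of the BH3-only genes Bcl2l11, Pmaip1 and Bik, of the fibronectin gene Fn1 and of cell cycle genes. They had higher levels of genes of hypoxia and glycolysis and of the integrated stress and unfolded protein responses. By the q-value of the authors' deposited table, 3737 of 12960 genes tested differed (28.8%), 1904 higher and 1833 lower in JNK-deficient cells. Of these, 1409 differed by at least 1.5-fold, 755 higher and 654 lower. Fbln2, a matrix protein gene, was at 16.2 FPKM in control and 0.524 FPKM in JNK-deficient cells (log2 -4.95, q = 0.000347) in the authors' deposited table. Havcr1, a marker of kidney tubule injury, was at 36.0 and 2.26 FPKM (-3.99), and the claudin gene Cldn1 at 10.4 and 0.899 FPKM (-3.54) in the authors' deposited table (q = 0.000347 each). The other 3 of the 6 largest falls were Tbc1d9 (-3.09), Dusp8 (-3.02) and Fn1 (-2.96) in the authors' deposited table. The 5 largest rises were those of the Notch ligand gene Jag2 from 0.819 to 15.6 FPKM (4.25), Meox2 (3.85), the chemokine gene Cxcl5 (3.63), Setd4 (3.22), and Inmt from 201 to 1767 FPKM (3.14) in the authors' deposited table.

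Of the 7 BH3-only genes tested in attached cells, 1 was higher and 4 were lower in JNK-deficient cells (1 and 5 adjusted over the list alone; FDR = 0.0626). Pmaip1 was at 70.9 and 39.9 FPKM (-0.83), Bcl2l11 at 9.43 and 5.42 FPKM (-0.80), Bik at -0.55 and Bbc3 at -0.32 (q = 0.00503) in the authors' deposited table. Bad was higher (0.48, q = 0.00152), and Bmf (-0.21, q = 0.0961) and Bid (0.02, q = 0.914) did not pass in the authors' deposited table. AP-1 and immediate early genes had 5 of 22 higher and 12 lower (FDR = 0.0463), with Jun at 7.96 and 1.76 FPKM (-2.18), Atf3 at -1.63, Fosb at -1.28 and Jund at -1.13 in the authors' deposited table. This list did not pass with a preset correlation of 0.05 or on ranks. G2/M genes had 0 higher and 11 of 18 lower (0 and 14 adjusted over the list alone; FDR = 2.27e-06), with Bub1 at -0.47 and Top2a at -0.39 in the authors' deposited table. S-phase genes had 0 higher and 10 of 17 lower (0 and 12 adjusted over the list alone; FDR = 6.13e-06), with Mcm3 at -0.58 and Mcm2 at -0.48 in the authors' deposited table. Matrix genes Fn1, which encodes fibronectin, and Tnc were at -2.96 and -2.72 in the authors' deposited table, in a list with 3 of 8 higher and 2 lower, also adjusted over the list alone (FDR = 0.726).

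Genes of hypoxia and glycolysis had 13 of 16 members higher in attached JNK-deficient cells and 0 lower (FDR = 6.13e-06), with Egln3, an oxygen-sensing hydroxylase gene, from 0.965 to 5.38 FPKM (2.48), Adm at 1.27 and Vegfa at 0.99 in the authors' deposited table. Genes of the integrated stress and unfolded protein responses had 11 of 17 higher and 0 lower (FDR = 7.67e-06), with Psat1, of serine synthesis, at 0.84 and Xbp1 at 0.63 in the authors' deposited table. NRF2 targets had 6 of 9 higher and 1 lower (FDR = 0.0154), with Nqo1 at 1.53, Gclc at 1.21 and Hmox1 at 1.09 in the authors' deposited table. Cholesterol genes had 10 of 21 higher and 2 lower (12 and 2 adjusted over the list alone; FDR = 0.00796), with Stard4 at 0.51 but Dhcr7 at -0.55 in the authors' deposited table. Distal tubule genes had 3 of 5 higher and 0 lower (4 and 0 adjusted over the list alone; FDR = 0.0128), Umod at 2.24, Avpr2 at 1.14 and Scnn1a at 0.91 in the authors' deposited table. NF-kB and inflammatory genes had 8 of 16 higher and 5 lower and did not pass (FDR = 0.28), with Ccl20 from 45.7 to 139 FPKM (1.61) and Ccl2 at 1.39 in the authors' deposited table. Counts adjusted over the list alone were the same except where given. The AP-1, cholesterol and NRF2 lists did not pass with a preset correlation of 0.05 (FDR = 0.178, 0.0656 and 0.0518), nor did the AP-1 list on ranks (0.0922) or the cholesterol list on log2(FPKM + 1) fold changes (0.38).

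In suspended cells, the genotype comparison asked what differs between the genotypes after 4 hours in suspension. Bcl2l11, Pmaip1, Bik, Jun, Atf3 and interferon-induced genes were lower and NRF2 targets higher in JNK-deficient cells. By the q-value of the authors' deposited table, 1600 of 12795 genes tested differed (12.5%), 713 higher and 887 lower, with 969 at a q-value below 0.01. The median derived standard error of genes at 16 to 64 FPKM was 0.153 here and 0.0911 in attached cells, so smaller differences could be called in attached cells. Havcr1 (-4.66), Dtx3 (-4.44), the MAP kinase phosphatase gene Dusp8 (-4.38), Nckipsd (-4.31) and Fhl1 (-3.78) were the 5 largest falls in the authors' deposited table. R3hdm2 (3.78), Renbp (3.67), Inmt (3.28), Cyba (3.07), Upk3b (2.99) and Pde10a (2.85) were the 6 largest rises in the authors' deposited table.

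Bcl2l11 was at 62.3 FPKM in suspended control and 28.0 FPKM in suspended JNK-deficient cells (-1.15, q = 0.00099) in the authors' deposited table. Pmaip1 was at 133 and 52.2 FPKM (-1.35, q = 0.00099) and Bik at 8.39 and 3.11 FPKM (-1.43, q = 0.00887) in the authors' deposited table. Bmf (-0.10, q = 0.766), Bbc3 (-0.41, q = 0.436), Bad (0.60, q = 0.263) and Bid (0.10, q = 0.729) did not pass in the authors' deposited table. That left 0 of 7 BH3-only genes higher and 3 lower, also adjusted over the list alone (FDR = 0.0578). Interferon-induced genes had 0 higher and 8 of 12 lower (0 and 10 adjusted over the list alone; FDR = 1.31e-07), with Rsad2 at 25.9 and 5.74 FPKM (-2.17), Usp18 at -1.98, Oasl2 at -1.78 and Oas1a at -1.61 in the authors' deposited table. AP-1 and immediate early genes had 2 of 20 higher and 9 lower (4 and 10 adjusted over the list alone; FDR = 0.0273), with Jun at -2.25, Atf3 at -2.12 and Dusp1 at -2.12, but Egr1 at 0.99 in the authors' deposited table. NF-kB and inflammatory genes had 2 of 15 higher and 5 lower (2 and 7 adjusted over the list alone; FDR = 0.023), with the adhesion receptor gene Icam1 at -1.94 and Cxcl2 at -0.97, but Lcn2 at 0.91 in the authors' deposited table. FOXO targets had 0 higher and 3 of 10 lower (0 and 4 adjusted over the list alone; FDR = 0.00559), Pik3ip1 at -1.31, Sesn3 at -1.04 and Fbxo32 at -0.61 in the authors' deposited table. P53 targets had 0 higher and 3 of 14 lower, also adjusted over the list alone (FDR = 0.0466), Btg2 at -1.22, Gdf15 at -0.80 and Mdm2 at -0.35 in the authors' deposited table. NRF2 targets had 8 of 10 higher and 0 lower, also adjusted over the list alone (FDR = 2.13e-07), with Nqo1 at 1.46, Hmox1 from 1153 to 2486 FPKM (1.11) and Gclc at 1.06 in the authors' deposited table. The AP-1, NF-kB and p53 lists did not pass with a preset correlation of 0.05 (FDR = 0.122, 0.0926 and 0.136). On log2(FPKM + 1) fold changes the FOXO, NF-kB and p53 lists did not pass (FDR = 0.0748, 0.1 and 0.297), nor did the AP-1 and p53 lists on ranks (0.159 and 0.0718).

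Part of the genotype differences was found in both states. Among 12251 genes tested in both, 1786 were higher and 1737 lower in attached JNK-deficient cells, and 690 and 814 in suspended ones. Of these, 505 were higher and 557 lower in both states, against 101 and 115 for independent lists, while 33 were higher in attached and lower in suspended cells and 1 was the opposite. Fold changes had r = 0.62 and rho = 0.52 across 12243 genes, and the comparisons share no libraries. Fn1 (-2.96 and -3.60), Havcr1 (-3.99 and -4.66) and Dusp8 (-3.02 and -4.38) were lower in both, and Inmt (3.14 and 3.28) and Egln3 (2.48 and 2.06) higher in both in the authors' deposited tables.

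The difference of the suspension effects asked whether the response depends on JNK. Interferon-induced genes had lower fold changes with suspension in JNK-deficient than in control cells, as did 5 of 15 NF-kB and inflammatory genes, and no BH3-only gene passed. Of 12765 genes tested, 230 differed (z-test, Benjamini-Hochberg), 70 with a higher and 160 with a lower fold change in JNK-deficient cells. The split was 43 and 185 after the GC and length correction, 30 and 125 through the genotype tables only, and 96 and 149 with standard errors from level alone. Of the 160, 33 rose in control and fell in JNK-deficient cells, 49 passed only in control cells, where they rose, and 32 passed only in JNK-deficient cells, where they fell. Of the 70, 25 rose in both genotypes and 7 fell in control and rose in JNK-deficient cells.

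**Figure D3:**
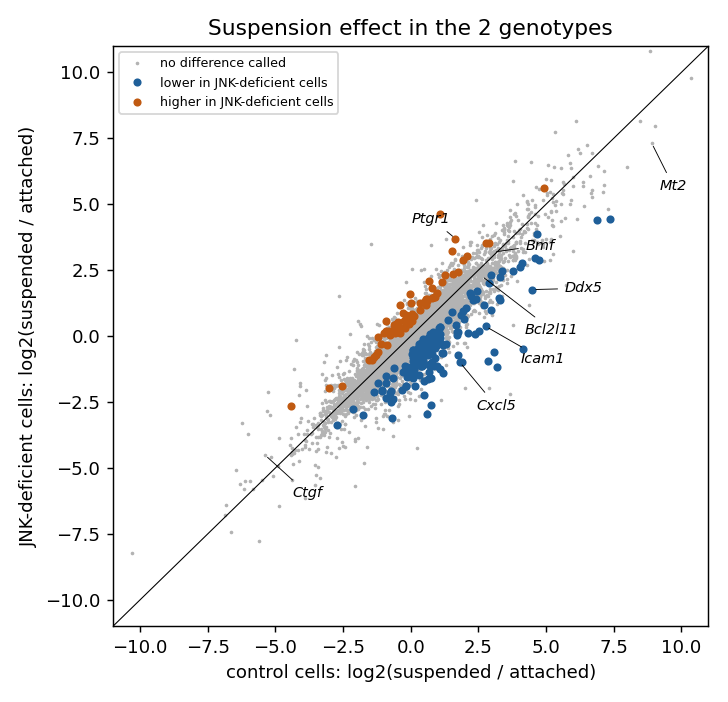
Log2 fold change with suspension in control (x axis) and JNK-deficient cells (y axis), 1 point per gene, with genes whose difference passed in colour and a line of equal change. The 160 genes in blue lie under the line and the 70 genes in orange above it, while Bcl2l11 and Bmf lie close to it.

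Interferon-induced genes had a median difference of -0.91, with 0 higher and 7 of 12 lower (0 and 12 adjusted over the list alone; FDR = 4.39e-21). Their median fold change with suspension was -0.24 in control and -1.33 in JNK-deficient cells, so the median was below 0 in both and lower in JNK-deficient cells. Isg15 was at -1.53 in control and -2.40 in JNK-deficient cells in the authors' deposited tables. Rsad2, an antiviral gene, had a fold change of 0.66 in control and -1.37 in JNK-deficient cells in the authors' deposited tables (difference -2.03, 95% interval -2.76 to -1.29, adjusted p = 6.3e-05). Oasl2 had 0.67 and -1.09 there in the authors' deposited tables (difference -1.76, -2.37 to -1.14, adjusted p = 5.4e-05). The standard errors of Rsad2 and Oasl2 are upper bounds, so their intervals may be too wide. In attached cells the same list did not pass for genotype (3 of 12 higher and 1 lower, also adjusted over the list alone; FDR = 0.292). NF-kB and inflammatory genes had a median difference of -0.28, with 0 higher and 5 of 15 lower (1 and 6 adjusted over the list alone; FDR = 2.13e-07). Its members past the threshold were Cxcl5 at -2.80, Ccl20 at -2.40, Icam1 at -2.40, Ccl2 at -1.54 and Nfkbia at -0.92. With the suspension tables only, Icam1, Ccl20 and Nfkbia did not pass (adjusted p = 0.0763, 0.156 and 0.166). Through the genotype tables only, Ccl2 and Cxcl5 did not (0.0542 and 0.0944). Cxcl5, Ccl20 and Ccl2 were already higher in attached JNK-deficient than in attached control cells, so their fold changes started from different levels. Icam1 went from 2.13 to 14.5 FPKM in control and from 2.83 to 3.65 FPKM in JNK-deficient cells in the authors' deposited tables. Cholesterol genes had a median difference of -0.22 (0 higher and 2 of 21 lower, 0 and 4 adjusted over the list alone; FDR = 6.13e-06), with Insig1 at -1.17. Hypoxia and glycolysis genes had a median of -0.20 (0 and 2 of 16, 0 and 3 adjusted over the list alone; FDR = 0.00144), with Bnip3 at -0.97. Stress response genes had a median of -0.14 (1 and 2 of 17, 1 and 5 adjusted over the list alone; FDR = 0.00231), with Herpud1 at -1.06 and Slc7a11 at -0.76 but the endoplasmic reticulum chaperone gene Hspa5 at 0.52. Distal tubule genes had a median of -0.84 (0 and 1 of 5, 0 and 3 adjusted over the list alone; FDR = 0.00133), with Scnn1a at -0.84. S-phase genes had a median of 0.29 with no member past the threshold (0 of 17, also adjusted over the list alone; FDR = 0.0132). NRF2 targets had a median of 0.18 (1 and 0 of 10, 3 and 0 adjusted over the list alone; FDR = 0.0331), with Srxn1 at 0.68. In attached and then suspended cells, median genotype fold changes were 0.37 and 0.01 for stress response and 0.20 and -0.07 for cholesterol genes. They were 0.43 and 0.27 for hypoxia and glycolysis, 0.91 and -0.19 for distal tubule and -0.36 and -0.08 for S-phase genes. These lists thus already differed before detachment, and less in suspension. NRF2 targets (0.47 and 0.74), NF-kB genes (0.24 and -0.39) and interferon-induced genes (0.10 and -0.72) differed more in suspension. With a preset correlation of 0.05 the S-phase and NRF2 lists did not pass (FDR = 0.0728 and 0.0926), nor did the NRF2 list on ranks (0.244) or with the difference also corrected for level (0.103).

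**Figure D4:**
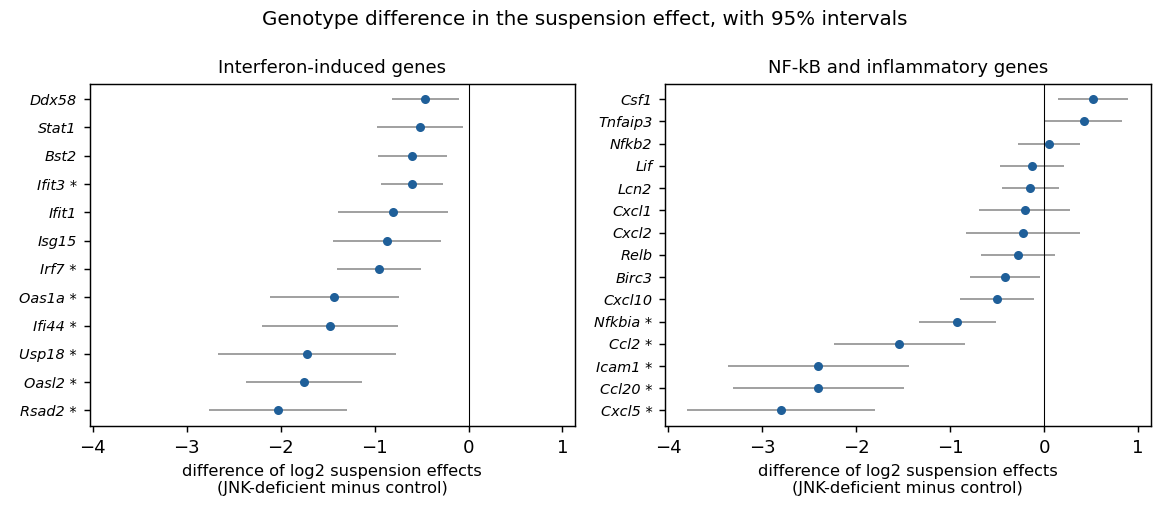
Difference of the suspension effects (x axis, JNK-deficient minus control, log2) of the 12 interferon-induced and 15 NF-kB and inflammatory genes tested, with bars for the 95% interval from the derived standard errors and a star on genes past the threshold. All 12 interferon-induced genes lie below 0, with a median of -0.91, and the inflammatory genes have a median of -0.28. For most starred genes the standard error is an upper bound.

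Among BH3-only genes the difference was -0.32 for Bcl2l11 (standard error at most 0.346, adjusted p = 0.858). It was -0.49 for Pmaip1 (95% interval -0.95 to -0.04, adjusted p = 0.381) and -0.85 for Bik (-1.71 to 0.02, adjusted p = 0.467). The standard errors of these 3 genes are upper bounds, and with those from level alone adjusted p was 0.878, 0.253 and 0.101. The other differences were 0.14 for Bmf (-0.21 to 0.49, adjusted p = 0.903), 0.15 for Bad (-0.54 to 0.84, adjusted p = 0.968), -0.06 for Bbc3 (-0.66 to 0.54, adjusted p = 0.988) and 0.11 for Bid (-0.19 to 0.42, adjusted p = 0.911). The list did not pass (FDR = 0.4; 0 of 7, also adjusted over the list alone). On simulated data the test called 18 of 50 genes made to differ by a log2 of 1, so smaller differences would mostly be missed. With standard errors multiplied by 1.5 no gene passed the z-test (0 of 12765, 354 at an unadjusted p under 0.05), and with standard errors from the suspension tables only, 103 did.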

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

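The tests with leukocyte markers, the corrections for GC content, length and level, and the standard errors from level or from 1 pair of tables were chosen only after the results were seen.

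The 230 genes whose response to suspension differed between genotypes stand out because the z-test found the difference itself, not because 1 genotype passed and the other did not. The count hangs on the derived standard errors, since 103 passed with those from the suspension tables only and 0 with all multiplied by 1.5. Both counts rest partly on upper bounds, which hold z down for genes with large fold changes whatever their spread. Of the 230, 44 genes are named here, and their differences (JNK-deficient minus control, log2) follow. Interferon-induced genes lay at -2.03 for Rsad2, -1.76 for Oasl2, -1.72 for Usp18, -1.48 for Ifi44, -1.43 for Oas1a, -0.95 for Irf7 and -0.60 for Ifit3. NF-kB and inflammatory genes lay at -2.80 for Cxcl5, -2.40 for Ccl20, -2.40 for Icam1, -1.54 for Ccl2 and -0.92 for Nfkbia. In attached cells, Cxcl5 and Ccl20 were higher in JNK-deficient cells (log2 3.63 and 1.61, q = 0.000347 each) in the authors' deposited table, so the groups started from different levels.

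Genes of cell structure and adhesion lay at -3.37 for Acta2, -0.62 for Fn1, -0.91 for Itgb6, -0.65 for Itgb3, 1.72 for Itgb8 and 1.11 for Sparc. Metabolic and transport genes lay at -1.17 for Insig1, -1.43 for Rragd, -0.76 for Slc7a11, -0.84 for Scnn1a and -0.97 for Lpin2. Stress genes lay at -1.06 for Herpud1, 0.52 for Hspa5, 0.74 for Manf, -0.83 for Hspb1, 0.68 for Srxn1, -0.97 for Bnip3 and -0.57 for Ddit4. Genes of transcriptional control lay at -0.85 for Btg2, -0.74 for Maff and 0.65 for Cited2. Genes named by the rule of another comparison lay at -4.65 for Dtx3, -3.58 for Setd4, 3.56 for R3hdm2 and -1.34 for Dusp8. The remaining differences were 2.05 for Ptgr1, 1.06 for the gap junction gene Gja1, 1.02 for Rasa3 and 0.95 for Anxa8. They were -1.33 for Neurl3, -2.73 for Ddx5 and 0.97 for Rn45s, the ribosomal RNA precursor. Messenger RNA was purified, so how far the Rn45s value reflects ribosomal RNA left in the libraries is unknown. After the correction for GC content and length, Ddit4 and Hspa5 no longer passed (adjusted p = 0.105 and 0.112), nor did Itgb3 with level corrected too (0.0581). With standard errors from level alone, 11 of the 44 did not pass. These were Itgb8 (adjusted p = 0.872), Dusp8 (0.855), Itgb3 (0.666), Scnn1a (0.368), Sparc (0.144), Fn1 (0.143), Hspa5 (0.0943), Rasa3 (0.0843), Slc7a11 (0.0763), Ddit4 (0.0614) and Maff (0.0563). With standard errors from the suspension tables only, 22 of the 44 did not pass, among them Icam1 (0.0763), R3hdm2 (0.169), Ccl20 (0.156), Nfkbia (0.166), Irf7 (0.582) and Ifit3 (0.988). Ddx5 (0.543), Ptgr1 (0.677), Bnip3 (0.798), Lpin2 (0.843), and Srxn1, Slc7a11, Rragd and Anxa8 (0.99998 each) were also lost there. Where both suspension p-values are at their lowest step, genes that change alike in both genotypes can hardly pass there. Such a loss says little about their spread. Through the genotype tables only, 11 did not, among them Ccl2 (0.0542), Cxcl5 (0.0944) and Dusp8 (0.825). At a q-value below 0.01, 14 did not.

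The list test of the difference picked out 8 lists. The median differences were -0.91 for interferon-induced genes, -0.28 for NF-kB and inflammatory genes, -0.22 for cholesterol genes and -0.14 for stress response genes. They were -0.20 for hypoxia and glycolysis genes, -0.84 for distal tubule genes, 0.29 for S-phase genes and 0.18 for NRF2 targets. By their median genotype fold changes, the stress response, cholesterol, hypoxia, distal tubule and S-phase lists differed more in attached than in suspended cells.

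For the interferon-induced genes, all 12 differences were below 0. The tables argue against GC content, length and level of the genes as the cause, since the median difference was -0.91 before and -0.97 after the correction for all of these (ratio 1.06). A lower share of leukocytes in the suspended JNK-deficient cultures stays open. Leukocyte markers had a median genotype fold change of 0.31 in suspended cells against -0.72 for the interferon-induced genes (difference 1.03). With 5 markers, from -1.12 to 1.09, this difference did not pass an exact two-sided permutation test that swapped genes between the lists (p = 0.0774, 6188 regroupings). Genes are not independent replicates, so this p-value does not measure the spread between cultures. Loss of JNK may lower the level of interferon-induced genes in suspended cells (median fold change with suspension -0.24 in control and -1.33 in JNK-deficient cells), a hypothesis found and tested on the same data. The values per group cannot tell this from a difference between cultures in exposure to interferon, which no table here measures.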

How the results depend on the processing

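The settings that correct for GC content, length or level, that take standard errors from level or from 1 pair of tables, and those of the genotype overlap were chosen only after the data were seen. No paired analysis was possible because the tables hold 1 value per group and none per sample, and for the same reason no sample could be left out. Of 53 alternative values of the counts that answer a comparison, 42 lay within 1.5 times the main count. Among these 42, recomputing the Benjamini-Hochberg adjustment and centring fold changes on their median left every pairwise count unchanged. These settings could hardly move the counts and say little about how firm they are. The cause of the moves below was not tested, except that a stricter threshold or minimum change calls fewer genes by construction. For the genotype effect, at least 1.5-fold gave 1409 genes in attached cells (3737 in all), and 1.5-fold on log2(FPKM + 1) gave 789 in attached and 984 in suspended cells (1600 in all), where a q-value below 0.01 gave 969. Suspension gave 6110 genes in control and 5766 in JNK-deficient cells at least 1.5-fold, and 5278 and 5031 at least 1.5-fold on log2(FPKM + 1). At a q-value below 0.01, 670 genes differed between genotypes alike in both states (1062 at 0.05) and 100 genes had a different response to suspension (18 higher and 82 lower, against 70 and 160 of 230 at 0.05). That last count was 103 with standard errors from the suspension tables only, 211 with the correction for GC content, length and level, and 0 with standard errors multiplied by 1.5 (z-test; 354 at an unadjusted p under 0.05, smallest adjusted p = 0.308). With a preset correlation of 0.05, 22 of the 36 pairs of list and comparison passed, none in the opposite direction. With the correction for GC content and length, 19 of 385 fold changes of named genes lost their call. Many of these genes were picked for large changes, and some had no call to lose. Over all genes, 6455 of 8428 suspension calls in control and 5186 of 7580 in JNK-deficient cells were kept in the same direction. The depth per sample is unknown, and an adjusted p beside a derived standard error is only as good as that error.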

Other observations

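The tests with transcript length and with the trend in JNK-deficient cells were chosen only after the result was seen.

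Several other gene lists did not pass for suspension, and single members changed. P53 targets had 10 of 14 members up and 3 down in control cells (the same adjusted over the list alone; FDR = 0.0678) and 8 up and 4 down in JNK-deficient cells (9 and 4 adjusted over the list alone; FDR = 0.234). Fas, a death receptor gene, rose from 0.92 to 9.86 FPKM in control and from 0.857 to 7.62 FPKM in JNK-deficient cells in the authors' deposited tables, while Gdf15 fell from 1042 to 50.4 FPKM in control cells. Heat shock genes had 1 of 10 up and 6 down in control cells and 1 up and 7 down in JNK-deficient cells, also adjusted over the list alone (FDR = 0.137 and 0.14), with Hspa1b at -3.32 and -3.74 in the authors' deposited tables. G2/M genes had 6 of 18 up and 2 down in control and 6 up and 1 down in JNK-deficient cells, also adjusted over the list alone (FDR = 0.342 and 0.104). Mesenchymal genes had 4 of 8 up and 3 down in control and 5 up and 3 down in JNK-deficient cells, also adjusted over the list alone (FDR = 0.714 and 0.468). Vim, which encodes vimentin, rose from 6.21 to 34.9 FPKM and Twist2 fell (-3.24) in control cells in the authors' deposited table. Integrin genes had 6 of 12 up and 5 down in control cells and 4 up and 6 down in JNK-deficient cells (4 and 7 adjusted over the list alone; FDR = 0.894 and 0.563). Itga3 fell from 545 to 105 FPKM and Itgb8 rose (1.52) in control cells in the authors' deposited table.

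Markers of cell types other than tubule epithelium were mostly too low to test. Of 9 fibroblast markers, 0 were tested in attached cells and 1 in the other comparisons. The marker tested rose with suspension in both genotypes, also adjusted over the list alone. In suspended cells the marker tested was lower in JNK-deficient cells. Of 7 endothelial markers, 4 were tested for suspension in control cells, with 2 up and 1 down (the same adjusted over the list alone; FDR = 0.563), and 2 in JNK-deficient cells, with 0 up and 1 down, also adjusted over the list alone. Endothelial Pecam1 went from 0.0241 to 0.583 FPKM in control cells in the authors' deposited table. Of 5 podocyte markers 2 were tested, and both rose with suspension in both genotypes, also adjusted over the list alone. Proximal tubule genes had 1 of 3 up and 1 down in control and 1 up and 2 down in JNK-deficient cells, also adjusted over the list alone (FDR = 0.925 and 0.733), with the water channel gene Aqp1 at -0.83 in JNK-deficient cells in the authors' deposited table.

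The fold changes of both suspension comparisons fell with transcript GC content. Transcript length was argued against, since among genes of like length the median rho with GC content was still -0.335 in control cells. A GC bias of the libraries of suspended cells may account for it. The ribosomal protein genes, whose products are needed in equal numbers, showed the trend too. Across 82 of them rho was -0.395 in control cells (95% bootstrap interval -0.587 to -0.17), at a slope of -0.0907 log2 units per percent GC. For genotype, rho across them was -0.328 in attached and -0.258 in suspended cells, at slopes of -0.0121 and -0.0136. Across all genes it was only -0.01 and -0.12 there. A negative rho across these genes thus also arose where all genes showed little trend. Decay of GC-rich transcripts would give the same sign, so these genes cannot decide for a library bias. A response of the cells to suspension, such as decay of GC-rich transcripts, stays open, since the trend was there in JNK-deficient cells too (rho = -0.418) and every suspended library is from suspended cells, so the bias and the response cannot be told apart.

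Genes near Mapk8 and Mapk9 were examined for a passenger segment of another strain, which could come with a targeted allele. Of 201 genes tested within 10 Mb of either gene, 22 differed between genotypes in the same direction in both states (10.9%), against 1038 of 12048 elsewhere (8.62%; ratio 1.27; Fisher's exact test, two-sided p = 0.253). This test does not settle the matter, since few genes lie near the loci and a smaller segment would hold fewer still.

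Some single values stood out and were not explained. Ddx5, an RNA helicase gene, was at 343 FPKM in attached and 7702 FPKM in suspended control cells, and at 946 and 3210 FPKM in JNK-deficient cells, in the authors' deposited tables. Rn45s went from 99.9 to 69.4 FPKM in control and from 82.6 to 112 FPKM in JNK-deficient cells there, though messenger RNA was purified. Rpl36, a ribosomal protein gene, went from 845 to 12.2 FPKM in control and from 751 to 16.6 FPKM in JNK-deficient cells in the authors' deposited tables. Ribosomal protein genes have many processed pseudogenes, and the tables do not say how reads shared with them were assigned.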
